A study of Rattus norvegicus with 10 samples.

How the data were processed

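Mammary tumours of female Sprague-Dawley rats were measured on 1-colour (Cy3) Agilent whole rat genome arrays, with 1 array per tumour and 200 ng of total RNA per labelling. The labels put 5 tumours in the maternal Western-style diet group and 5 in the maternal control diet group. The labels do not say whether the tumours of a group came from separate dams or litters, so no p-value measures the spread between dams or litters. The p-values of single genes and of permutations of the group names measure the spread between tumours only. The number of arrays limits the precision.

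Per the file headers, the authors read each scanned array with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name version 15.5. The deposited array files give spot intensity values as processed signals, which per the file headers are background-subtracted and not scaled between arrays. They also give intensity values for the median pixel of each spot and of its local background. The same deposited files hold marks of 0 or 1 per spot for a signal well above background, for outlier spots and for saturated spots. The deposited series matrix holds log2 values. These were found to be quantile-normalised median spot signals without background subtraction, a reading inferred from the values. The rank order of each matrix column was that of its own array's median signals (Spearman correlation 1 for all 10 arrays), and the column medians lay between 6.97 and 6.98. The tool that made the matrix is not given in the sources used here.

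Each array held 45018 spots, of which 1639 were controls and 43379 were measuring spots of 41012 probes. The processed signals were taken to log2, and the 75th percentile of the measuring spots of each array was subtracted. All levels below are on this scale, so a level of 0 is the 75th percentile of the array. Spots marked as outliers were left out, and the spots of a probe were averaged. A probe was kept when it was well above background on at least 5 of the 10 arrays, which left 19725 probes. The RefSeq annotation of the GRCr8 assembly was used for gene names only. It matched 17502 probes (42.7%) through their transcript identifiers (17437 NM, 47 XM and 18 NR identifiers), and 23510 probes had no name from it. The coordinates in the array annotation are on the rn4 build, which differs from GRCr8, so no positions are given. Of several kept probes of a gene, the one with the highest mean level was used. That gave 16764 genes, 8260 of them with a symbol. Of the 2442 genes with several kept probes, 967 had probes with differences in both directions, and 7 of these had probes in both directions each at an unadjusted p under 0.05.

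Slide and scan were read from the array numbers and headers. The arrays lay on 3 slides, each of which held both groups, and each slide had its own scan, so slide and scan cannot be told apart. Slide 1 held 2 Western-style diet tumours and 1 control tumour, slide 2 held 2 and 2, and slide 3 held 1 and 2.

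Genes were compared with limma 3.58.1 in R 4.3.3 (linear model with moderated variances, Benjamini-Hochberg adjustment over all tested genes, adjusted p under 0.05), with files read by the data.table package, version 1.17.8. Differences are Western-style minus control. Of 38 gene lists fixed by name, the 35 with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, which asks whether a list's genes differ more than other genes do. Camera was also run with an estimated correlation, and fry, also in limma, was run as a test of whether a list's genes move one way. At the preset correlation camera counts a list's genes as nearly independent, so its p-values do not measure the spread between tumours alone. A list's level in a tumour is the mean of its measured members. Levels, principal components and the spread between tumours were compared by exact two-sided permutation of the group names, which cannot give a p below 0.0079. Slide effects on the components were tested by random permutation. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

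The groups, the tests, the lists, the rule for named genes and most of the alternatives were fixed before the data were examined. The rule took 4 sets of genes. The first set is the genes past the threshold, up to 10 in each direction. A direction with fewer than 6 is filled to 6 with symbol-bearing genes of smallest unadjusted p and a difference of at least 1 (log2). The second set is the 4 members of smallest p of each called list, and the third is the 1 member of smallest p of every other list. The fourth set is 15 genes fixed by name, of which Mki67, Adipoq and Lep were not kept by the filter. In all, 89 named genes were tested.

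The procedure was tested on simulated data of the same size, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 46% and 92% of them, with 9 false calls among 147. Without any change it called 846 genes at an unadjusted p under 0.05 and 0 at an adjusted p. A simulated shift of a list gave an adjusted p of 0.000214 with camera, with 0 of the other lists called among 35. The simulated genes varied independently of each other. This simulation therefore cannot show how often camera calls a list whose members are correlated.

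The alternatives tried were quantile normalisation, median scaling, the series matrix values, other filters (none, at least 3 arrays, all arrays), the mean of a gene's probes, every probe on its own, outlier spots kept, slide or replicate number as a block, a variance trend with robust moderation, array weights, and leaving out each tumour in turn. The normexp background correction (offset 50) had been planned on mean spot signals, which are not used here, so it was run on median spot signals, with and without quantile normalisation. Those forms of normexp, array brightness as a covariate, and leaving out the 3 dimmest arrays were chosen after seeing the data.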

Results

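The series asks whether the diet of rat dams alters gene expression in mammary tumours of their daughters. Dams ate a control diet or a Western-style diet (high in fat, low in fibre and trace elements) from gestational day 12 to 20 and from postnatal day 1 to 21. All daughters ate control diet after weaning and were given the alkylating carcinogen N-methyl-N-nitrosourea (50 mg/kg) at the age of 3 weeks. Tumours were measured at 110 days, 5 in each group. Replicates are written WD1 to WD5 (maternal Western-style diet) and CD1 to CD5 (maternal control diet). The 75th percentile of spot intensity lay between 72.8 and 170 in the Western-style diet group and between 85.1 and 226 in the control group. Between 16684 and 21906 probes per array were well above background, and pairs of arrays had Pearson correlations over tested genes of 0.915 to 0.977.

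Tumours from the Western-style diet group had higher levels of T cell, macrophage, matrix and inflammatory genes and lower levels of cell cycle, mast cell and mitochondrial energy genes, as lists called by camera (adjusted p = 0.613 to 0.697 with an estimated correlation). T cell receptor gene Cd3e was 1.94-fold higher and the neutrophil attractant Cxcl1 3.30-fold higher, while the mast cell tryptase Tpsb2 was 2.31-fold lower and the replication factor Mcm7 1.71-fold lower. The estrogen and progesterone receptor genes Esr1 and Pgr and the keratin genes Krt8 and Krt19 had lower levels in all 5 Western-style diet tumours than the control mean. Esr1 was not well above background on any of those 5 arrays. Krt8 and Krt19 were the luminal epithelial genes of smallest p. Of the 15 measured luminal genes 6 were higher, and that list was not called by camera (-0.16, adjusted p 0.300). No single gene passed the test, and the list results rest on a preset correlation between genes of 0.01. The estimated correlations of the called lists ran from 0.10 (fatty acid oxidation) to 0.86 (cell cycle). By exact permutation of list levels 0 lists passed (lowest adjusted p 0.278). Of 100 drawn splits of the tumours, the real one included, 21 called as many lists. With array brightness as a covariate the cell cycle list was not called and the T and NK cell shift was 0.43 instead of 0.79.

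In limma, 0 of 16764 genes had an adjusted p under 0.05 (lowest 0.136). At an unadjusted p under 0.05 there were 2599 genes, 1307 higher and 1292 lower, where chance gives 838. That count depends on the processing: with normexp background correction it was 496 (352 higher, 144 lower), below the chance count, and without a filter on dim probes 7050 (5995 higher, 1055 lower; chance gives 1801). Of the 2599 genes, 272 differed by at least 1 on the log2 scale, 177 higher and 95 lower. The groups did not overlap for 610 genes (3.64% of those tested), where chance gives 0.794%. The median difference of all genes was 0.01 and the median residual SD was 0.34 (log2).

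Of the symbol-bearing genes with differences of at least 1, the 6 of smallest p in each direction were taken, of which 11 follow and 1 higher gene is not reported here; none of the 11 passed (adjusted p 0.136 to 0.181). Tppp3 (probe A_43_P11040), of a family that promotes tubulin assembly, was 3.18 ± 0.47 (SD, n = 5) against 1.54 ± 0.41 (n = 5) in log2 units, which is 3.12-fold higher. Arhgap30 (A_44_P744421) was -0.88 ± 0.27 against -2.03 ± 0.29, which is 2.22-fold higher. Zc3h12d (A_44_P945723), a zinc finger gene of immune cells, was 2.54-fold higher. Adam19 (A_42_P601971), a metalloprotease, and Pim1 (A_43_P11786), a kinase induced by cytokines, were 2.32-fold and 2.47-fold higher. Ptdss2 (A_44_P203682), which makes phosphatidylserine, was -3.37 ± 0.61 (SD, n = 5) against -1.78 ± 0.34 (n = 5), which is 3.01-fold lower. Phf13 (A_44_P390385), a chromatin reader, was 2.64-fold lower, and Klhl25 (A_44_P203640), a ubiquitin ligase adaptor, was 2.23-fold lower. These 3 genes were well above background on 1 of 5 Western-style diet arrays, so their size is uncertain. Plbd1 (A_42_P463880) was 2.52-fold lower, Cirbp (A_44_P138790), a cold-inducible RNA-binding protein, 2.02-fold lower, and Pepd (A_43_P20408), prolidase, 2.30-fold lower. All 11 genes differed from the control mean in the same direction in 5 of 5 Western-style diet tumours, and 10 kept their sign within all 3 slides. As the genes were picked for a small p in these same arrays, both counts were likely in advance and are no separate support. Pepd differed by 0.21 in the other direction on slide 3. Low levels were not limited to lower genes: Arhgap30, Zc3h12d, Adam19 and Pim1 had control means from -2.28 to -1.85. With array brightness as a covariate the lowest adjusted p of any gene in limma was 0.856.

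**Figure D1:**
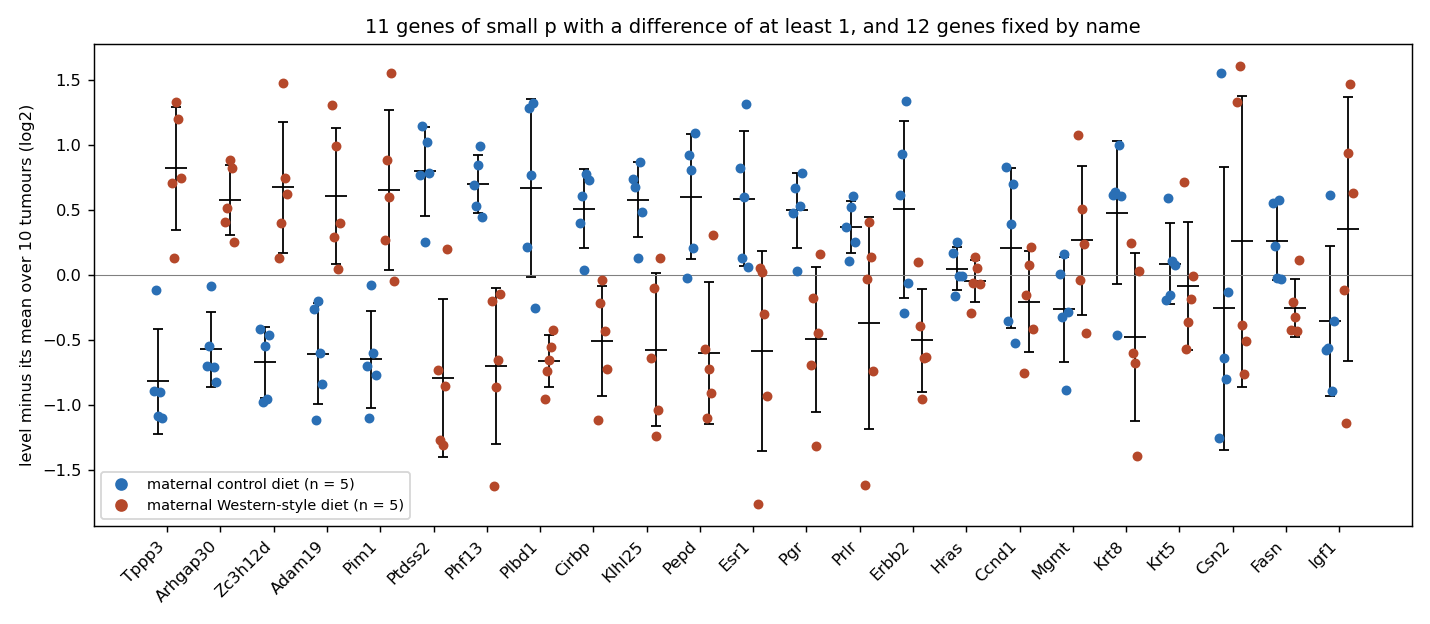
Levels of 23 genes in each tumour (points; log2 level minus the mean of the 10 tumours), with the mean and SD of each group (n = 5) as black bars. The first 11 are of the 12 symbol-bearing genes taken, 6 in each direction, by smallest p among differences of at least 1 (log2), and the other 12 were fixed by name; none passed the test (lowest adjusted p 0.136).

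The T and NK cell, macrophage, fibroblast and MHC class II lists were called higher in the Western-style diet group. All 10 measured T and NK cell genes were higher, by a mean of 0.79 (adjusted p = 0.00208, 4 of 5 tumours above the control mean), with adjusted p = 0.613 with an estimated correlation; with array brightness as a covariate the shift was 0.43 (adjusted p 0.0336). Zap70, a T cell receptor kinase, was 2.05-fold higher, and Cd3g, Cd3e and Cd3d were 2.07-fold, 1.94-fold and 1.76-fold higher. Adjusted over the list alone 4 members passed, and over all genes 0. All 16 macrophage and monocyte genes were higher, by a mean of 0.53 (adjusted p = 0.00633, 4 of 5 tumours), with adjusted p = 0.656 with an estimated correlation. Laptm5, Mrc1, Fcgr1a and Tyrobp were 1.85-fold, 1.86-fold, 1.58-fold and 1.61-fold higher. All 18 fibroblast and extracellular matrix genes were higher, by a mean of 0.58 (adjusted p = 0.00633, 4 of 5 tumours), with adjusted p = 0.656 with an estimated correlation. The matrix proteins tenascin (Tnc), Fbn1, Fn1 and Postn were 1.94-fold, 1.71-fold, 1.93-fold and 1.78-fold higher, and a second probe of Fbn1 differed in the other direction. Of the 10 MHC class II genes 9 were higher, by a mean of 0.60 (adjusted p = 0.0188, 4 of 5 tumours), with adjusted p = 0.613 with an estimated correlation. RT1-DOb, Ciita (the master regulator of this class) and RT1-Bb were 2.74-fold, 2.12-fold and 1.80-fold higher, and the protease Ctsh was 1.51-fold lower. Adjusted over the list alone 2 of them passed, both higher, and over all genes 0. RT1-DOb and Ciita were well above background on 1 and 2 of the 5 control arrays. The macrophage and MHC class II lists share 1 member, Ctss.

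Of 14 inflammatory cytokine and NF-kB target genes 11 were higher, by a mean of 0.75 (adjusted p = 0.0269, 4 of 5 tumours), with adjusted p = 0.613 with an estimated correlation. The monocyte attractants Ccl7 and Ccl2 were 2.55-fold and 2.15-fold higher, Cxcl1 was 3.30-fold higher and Il1b 2.76-fold higher. WD4 had the highest Il1b level, 4.01, where the other Western-style diet tumours lay between -0.32 and 0.94. Of 22 epithelial-mesenchymal transition and invasion genes 17 were higher, by a mean of 0.34 (adjusted p = 0.0363, 4 of 5 tumours), with adjusted p = 0.613 with an estimated correlation; with array brightness as a covariate this list was not called (0.26, adjusted p 0.0515). Tgfb2, S100a4 and Plaur were 1.78-fold, 1.94-fold and 1.76-fold higher, while Snai2, a transcription factor of this programme, was 2.43-fold lower. Snai2 was well above background on 2 of 5 Western-style diet arrays and Plaur on 2 of 5 control arrays, so their size is uncertain. In these 2 lists and in the macrophage and matrix lists 0 members passed adjusted over the list alone, as over all genes.

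Proliferation, mast cell and mitochondrial lists were lower. Of 27 cell cycle genes 25 were lower, by a mean of -0.48 (adjusted p = 0.00633), with adjusted p = 0.697 with an estimated correlation, and 3 of 5 tumours lay below the control mean. With array brightness as a covariate the cell cycle list was not called (-0.22, adjusted p 0.251). Mcm7, Aurka, Rrm1 and Mcm3 were 1.71-fold, 2.10-fold, 1.63-fold and 1.58-fold lower, and a further probe of Rrm1 differed in the other direction. Of 7 mast cell genes 6 were lower, by a mean of -0.98 (adjusted p = 0.0269, 4 of 5 tumours), with adjusted p = 0.613 with an estimated correlation. The mast cell proteases Tpsb2, Cpa3 and Mcpt1 were 2.31-fold, 2.33-fold and 2.14-fold lower, and Hdc, which makes histamine, was 3.10-fold lower. The folds of Hdc, Cpa3 and Mcpt1 rest in part on WD1. Its Hdc level was -4.44, where the other Western-style diet tumours lay between -1.34 and 0.71. Its Cpa3 level was -2.19 (others -0.48 to 1.28) and its Mcpt1 level -1.21 (others 0.56 to 2.29). Of 20 fatty acid oxidation genes 15 were lower, by a mean of -0.21 (adjusted p = 0.00633, 5 of 5 tumours), with adjusted p = 0.613 with an estimated correlation. Acaa2, Cpt1a (which admits fatty acids to the mitochondrion), Echs1 and Hadhb were 1.59-fold, 1.52-fold, 1.42-fold and 1.39-fold lower. Adjusted over the list alone 2 of them passed, both lower, and over all genes 0. Of 31 oxidative phosphorylation genes 23 were lower, by a mean of -0.17 (adjusted p = 0.00633, 5 of 5 tumours), with adjusted p = 0.613 with an estimated correlation. The ATP synthase genes Atp5f1a and Atp5f1b were 1.56-fold and 1.67-fold lower, and Ndufs3 and Ndufa9 of complex I were 1.30-fold and 1.29-fold lower. Adjusted over the list alone 1 passed, and over all genes 0. In the cell cycle and mast cell lists 0 members passed adjusted over the list alone, as over all genes.

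**Figure D2:**
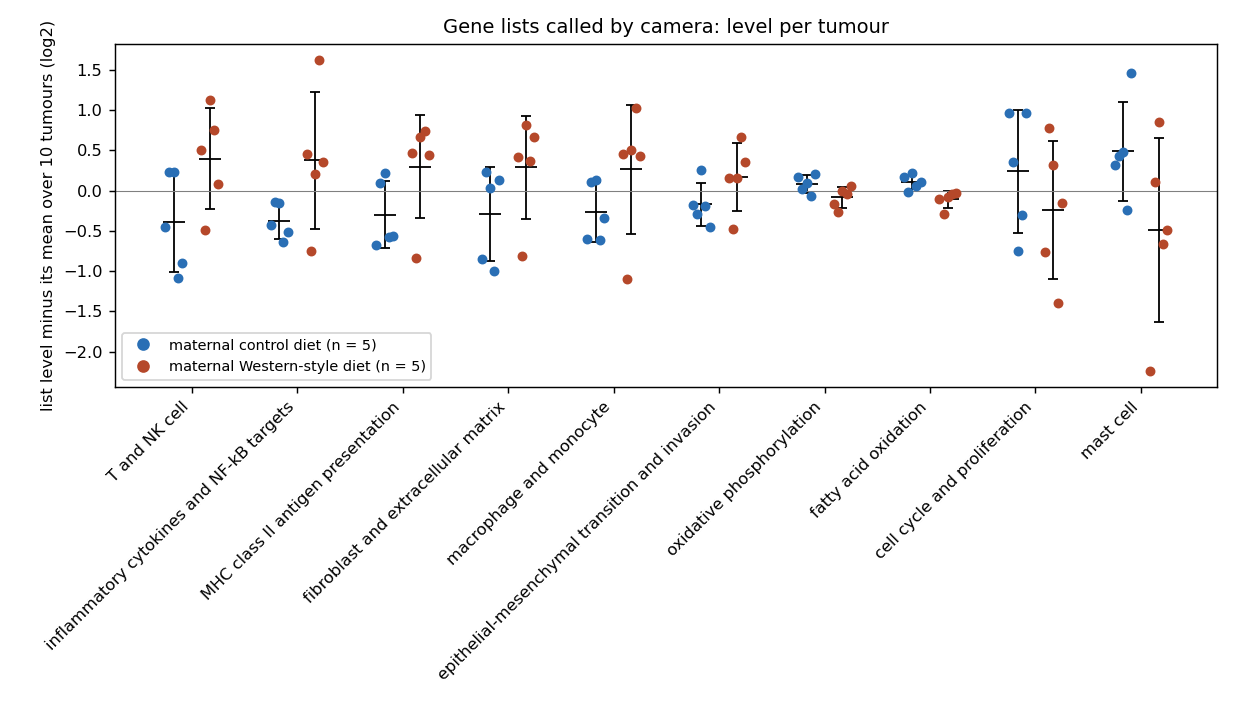
Level of each of the 10 lists called by camera in each tumour (points; mean log2 level of the list's measured genes minus the mean of the 10 tumours), with the mean and SD of each group (n = 5) as black bars. Differences between groups run from 0.79 for T and NK cell genes to -0.98 for mast cell genes, and WD2 is the lowest Western-style diet tumour in the T cell, inflammatory, MHC class II, fibroblast and macrophage lists.

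Camera called 10 of 35 lists, with an estimated correlation it called 0, and fry called 0 (lowest adjusted p 0.129). By exact permutation of list levels 0 lists passed after adjustment (lowest adjusted p 0.278), and 2 had an unadjusted p under 0.05. These were fatty acid oxidation at 0.0079, the smallest these groups allow, and epigenetic modifiers at 0.0159. With array brightness as a covariate the epigenetic modifier shift was -0.087 instead of -0.16, and the fatty acid oxidation shift -0.22 instead of -0.21. Within slides 1, 2 and 3 the T and NK cell shift was -0.23, 1.27 and 0.85, the macrophage shift -0.43, 0.88 and 1.04, the fibroblast shift -0.43, 0.51 and 1.58, the MHC class II shift -0.27, 0.88 and 1.06, the inflammatory shift -0.01, 1.25 and 0.88 and the oxidative phosphorylation shift -0.24, -0.18 and 0.01. The other 4 called lists kept their sign on all 3 slides, and with slide as a block the 10 shifts lay between -0.96 and 0.79.

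The list count was 1 without WD1, 4 without WD4, 5 without WD5, 4 without CD5 and 7 to 10 without any of the other tumours. The T and NK cell call held without each of the 10 tumours, with shifts from 0.60 to 1.01. The fatty acid oxidation call was lost without WD1 (shifts -0.24 to -0.17), the macrophage call without WD1 or WD4 (0.35 without WD4, 0.87 without WD2) and the fibroblast call without WD1, WD5 or CD1 (0.40 to 0.85). The oxidative phosphorylation call was lost without WD1, WD2 or CD5 (-0.21 to -0.13) and the cell cycle call without WD1, WD4, CD1 or CD5. The cell cycle shift was -0.20 without WD4, -0.30 without CD1 or CD5, -0.73 without CD3 and -0.74 without WD2. The mast cell and inflammatory calls were each lost without WD1, WD4, WD5, CD3 or CD5, with a mast cell shift of -0.54 without WD1 and an inflammatory shift of 0.44 without WD4. The MHC class II call was lost without WD1, WD3, WD4, WD5 or CD5 and the epithelial-mesenchymal transition call without WD1, WD4, WD5, CD1, CD2 or CD5, with shifts of 0.39 and 0.23 without WD4.

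Single genes fixed by name did not pass. Pgr, the progesterone receptor, was 0.26 ± 0.56 (SD, n = 5) against 1.26 ± 0.29 (n = 5), which is 1.99-fold lower, and all 5 Western-style diet tumours lay below the control mean (adjusted p 0.181). Esr1, the estrogen receptor, was not well above background on any Western-style diet array and was on 5 of 5 control arrays (adjusted p 0.202, 5 of 5 tumours lower). As a bound, its level on each Western-style diet array was raised to the lowest level of any probe well above background there, where that was higher. At this bound it was 1.21-fold lower in the mean, a value that carries no sampling error. Erbb2, a growth factor receptor, was 2.02-fold lower (adjusted p 0.202, 5 of 5 tumours), and Prlr, the prolactin receptor, was 1.67-fold lower (adjusted p 0.320, 4 of 5 tumours). The luminal keratin genes Krt8 and Krt19 were 1.94-fold and 2.15-fold lower (adjusted p 0.232 and 0.213, 5 of 5 tumours). Of the 15 measured luminal epithelial genes 9 were lower and 6 higher. The basal keratin gene Krt5 was 1.12-fold lower (adjusted p 0.764, 4 of 5 tumours). Hras, a gene often mutated in this tumour model, differed 1.07-fold (adjusted p 0.766, 3 of 5 tumours lower), Ccnd1 1.33-fold (adjusted p 0.510, 4 of 5 lower) and Fasn, fatty acid synthase, 1.43-fold (adjusted p 0.228, 5 of 5 lower). Mgmt, which repairs the DNA damage done by this carcinogen, was 1.45-fold higher (adjusted p 0.391, 4 of 5 tumours), Igf1 1.63-fold higher (adjusted p 0.466, 4 of 5) and the milk protein Csn2 1.43-fold higher (adjusted p 0.702, 2 of 5). Csn2 was well above background on 3 of 5 Western-style diet arrays and 4 of 5 control arrays, so its size is uncertain. The milk protein list differed the other way, by -0.42.

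The other 25 lists were not called (adjusted p 0.0809 to 0.895), of which 11 had higher and 14 lower mean levels. Estrogen, progesterone and prolactin signalling genes differed by -0.33 (adjusted p 0.0877, 5 of 5 tumours lower; -0.27 with Esr1 at its bound), and 1 member passed adjusted over the list alone. Epigenetic modifiers differed by -0.16 (adjusted p 0.0809, 5 of 5 lower), with Mbd3 1.62-fold lower, and fatty acid and triglyceride synthesis by -0.23 (adjusted p 0.0942, 5 of 5 lower; called with slide as a block, adjusted p 0.0381). Among other cell types, luminal epithelial genes differed by -0.16, basal and myoepithelial genes by -0.32 (Dsc3 2.30-fold lower), adipocyte genes by 0.46 (Cebpa 2.14-fold higher; called at 0.96 with array brightness as a covariate, adjusted p 0.00398), endothelial genes by 0.34 (Cdh5 1.59-fold higher) and neutrophil genes by 0.05 (Defa5 2.14-fold lower). Cebpa was 1.16 in WD1 and between -2.37 and -0.51 in the other Western-style diet tumours. Skeletal muscle genes differed by -0.03 (Myh2 1.91-fold higher, 1 member passing adjusted over the list alone) and Schwann cell genes by -0.02 (Gfap 1.68-fold higher). Milk protein genes differed by -0.42 (Mfge8 1.59-fold lower), DNA repair genes by -0.10 (Xpc 1.35-fold lower), insulin and IGF signalling genes by 0.25 (Akt1 1.62-fold lower) and cholesterol synthesis genes by 0.04 (Sc5d 1.51-fold lower). Glycolysis and hypoxia genes differed by -0.02 (Pgk1 1.70-fold lower), interferon response genes by 0.03 (Gbp2 1.48-fold higher), oncogenes and growth factor receptors by -0.08 and Wnt signalling genes by -0.03 (Fzd2 1.44-fold lower). Oxidative stress defence genes differed by -0.02 (Gstm2 1.93-fold lower) and unfolded protein response genes by 0.11 (Atf4 1.42-fold higher). Immediate early and heat shock genes, which respond to tissue handling, differed by 0.10 (Klf6 1.79-fold higher, 1 member passing adjusted over the list alone). Circadian clock genes differed by -0.25 (Nr1d2 1.59-fold lower, 2 members passing adjusted over the list alone), apoptosis and p53 targets by 0.06 (Perp 1.44-fold lower), trace element genes by 0.00010 (Tfrc 1.30-fold lower) and adipokine and appetite hormone receptor genes by 0.11 (Nampt 1.21-fold lower, with a second probe in the other direction). In 5 lists (trace element, adipokine, skeletal muscle, cholesterol and apoptosis) the mean, the median and the test differed in sign. In the uncalled lists with no such count given, 0 members passed adjusted over the list alone, and in all of them 0 passed over all genes. B and plasma cell, erythroid and cornified keratinocyte lists had 2, 3 and 4 measured members and were not tested; Pou2af1 was 1.51-fold lower, Alas2 2.85-fold lower and Krt1 1.66-fold higher (adjusted p 0.654, 0.335 and 0.267; 4, 4 and 5 of 5 tumours in that direction). The size is uncertain for Alas2, well above background on 1 of 5 Western-style diet arrays, for Cdh5, Defa5 and Nr1d2, on 2 of 5 of those arrays, and for Krt1, on 2 of 5 control arrays.

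Over all tested genes, principal component 1 (28.8% of the variance) differed between groups with an exact permutation p of 0.143 and component 2 (17%) with 0.579. Component 1 had an exact permutation p of 0.0159 without CD3, 0.0238 with median scaling, 0.0397 without a filter and 0.0286 without the 3 dimmest arrays, and component 2 had 0.0238 without WD3 or WD4, and 0.0238 and 0.0317 with the filters on all and on 3 arrays. A permutation test between slides gave p = 0.0541 and 0.687 for these components. The mean distance between tumours was 1.05 within the Western-style diet group and 0.996 within the control group, a difference of 0.0557 with an exact permutation p of 0.111. That difference was -0.00022 without WD2, -0.0054 with normexp and -0.046 without the 3 dimmest arrays, and 0.169 without CD3. Arrays of the Western-style diet group were dimmer, by -0.73 in the log2 of the 75th percentile (exact permutation p 0.0714; -0.66 with slide as a block, and -1.10, -0.71 and -0.15 within slides 1, 2 and 3). With that brightness as a covariate, an alternative chosen after seeing the data, 961 genes had an unadjusted p under 0.05. Without the 3 dimmest arrays (WD2, WD3 and CD3) there were 2800. Among the arrays then left, every Western-style diet array was dimmer than every control array (brightest 7.41 in WD5, dimmest control 7.56 in CD1). The 2800 genes therefore cannot speak for or against brightness. Of the 89 named genes 75 had the same sign within all 3 slides, and for 21 the groups did not overlap (3.64% of all tested genes). Most of the 89 were picked for a small p in these same arrays, which raises both counts, so they are no separate support. Under median scaling the median of all genes moved to -0.24 and 3303 of the genes at an unadjusted p under 0.05 were lower against 331 higher.

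**Figure D3:**
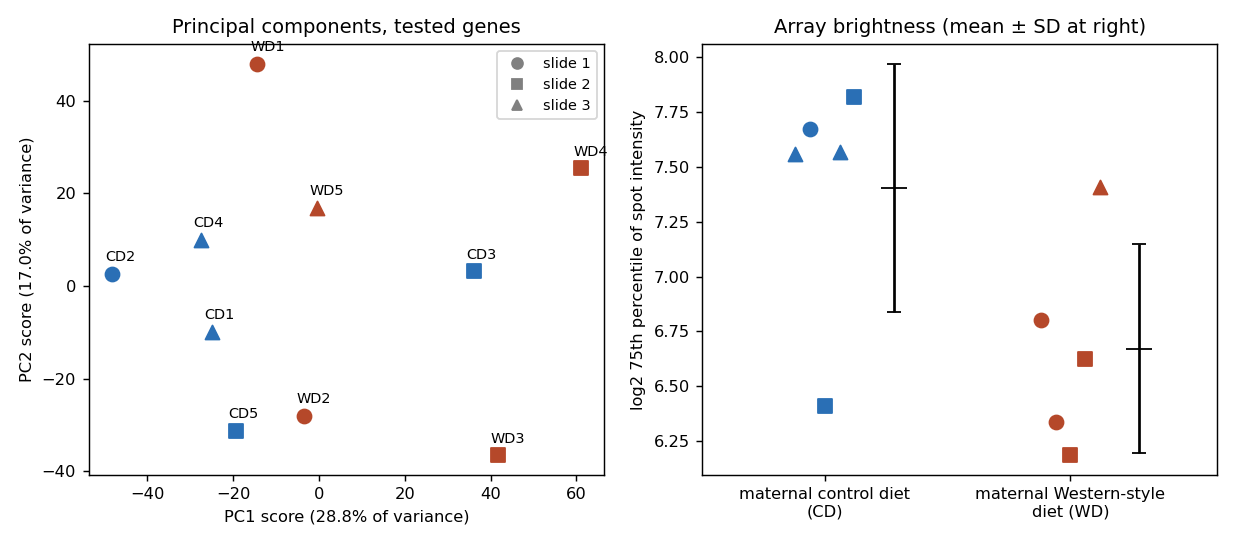
Left, the first 2 principal components of the tested genes, with 1 point per tumour, the shape showing the slide. Right, the log2 75th percentile of spot intensity of each array, with the mean and SD of each group (n = 5) as bars; it averaged 6.67 in the Western-style diet group and 7.40 in the control group, where CD3 stood apart at 6.41.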

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

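The tests of other splits of the tumours, of slide, of cell make-up and of the mean of Esr1, Pgr, Prlr and Erbb2, and the control with permuted brightness values, were chosen only after the results were seen; the array brightness tests were written down before any fit with brightness was run, though that alternative was added after seeing the data.

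In 254 comparisons of 5 tumours within a group, 15 had 1 tumour standing far from the other 4, where chance gives about 1 in 20, or 12.7. WD2 was the low tumour in 7 of them. Its fibroblast level was 1.28 (others 2.45 to 2.90), its macrophage level 1.34 (2.86 to 3.46), its MHC class II level 1.89 (3.16 to 3.47) and its unfolded protein response level 2.24 (2.49 to 2.57). WD2 also had the lowest Western-style diet levels of Fn1 at 2.34 (others 4.22 to 4.64), Mrc1 at -0.24 (1.38 to 1.90) and Ctsh at 1.97 (2.79 to 2.95). WD4 stood apart with a luminal epithelial level of 2.65 (2.96 to 3.04) and an Il1b level of 4.01 (-0.32 to 0.94). CD3 stood apart with Atp5f1b at 3.04 (others 3.78 to 4.05), Akt1 at 1.22 (2.02 to 2.09), Krt8 at 3.36 (4.43 to 4.82) and an array log2 75th percentile of 6.41 (7.56 to 7.82). CD2 had a Tppp3 level of 2.25 (1.26 to 1.46) and CD4 an Nr1d2 level of -1.68 (-1.18 to -1.01). No explanation of these single tumours was tested.

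The first pattern is the number of genes at an unadjusted p under 0.05, 2599 where chance gives 838. As many genes came from 4 of 100 drawn splits of the 10 tumours into 5 and 5, the real one included (highest other drawn split 3277). That share is low, but the test was chosen after the count was seen, so it does not exclude chance. With normexp the real split gave 496 genes, fewer than chance gives. Of the same 100 splits 41 gave as many (highest other 6624), so there too chance cannot be excluded. With slide as a block the count was 2910, which argues against slide as the whole cause. With array brightness as a covariate the count was 961, as the brightness explanation needs, and 3 of 100 draws with brightness permuted within groups (the real one included) gave a count as low (median 1804, range 786 to 4141). Among the 2599 genes the median size of the difference went from 0.61 to 0.43 and its median standard error from 0.21 to 0.24, with 680 still at an unadjusted p under 0.05, so brightness may account for a large part of the excess while maternal diet stays open and untested apart from it; a split of the 5 brightest against the 5 dimmest arrays gave 3084 genes, but it is the real split with WD5 and CD3 exchanged and so adds no separate support.

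At an adjusted p under 0.05 the real split gave 0 genes in limma, a count that all 100 drawn splits reach whatever their values, so the splits say nothing on chance for it. Of the 99 other drawn splits 8 gave any gene, and the highest count was 70; a structure of the samples can give such a count, and none was tested here.

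The second pattern is the 10 lists called by camera. Chance cannot be excluded, since 21 of 100 splits called as many (highest other drawn split 16). With array brightness as a covariate 8 of the 10 lists were called in the same direction by camera at the preset correlation. Without the covariate the same test called up to 16 lists in other drawn splits, so these 8 calls cannot decide on brightness. Over tumours, the shifts with the covariate (standard error) were fatty acid oxidation -0.22 (0.08), mast cell -1.26 (0.77) and oxidative phosphorylation -0.13 (0.10). They were inflammatory 0.79 (0.53), fibroblast 0.64 (0.52), macrophage 0.53 (0.54) and MHC class II 0.49 (0.46). The T and NK cell shift went from 0.79 to 0.43 (standard error over tumours 0.39 and 0.49). Adipocyte genes, uncalled at 0.46, were called by camera at 0.96 (adjusted p 0.00398). The cell cycle call ended with its shift going from -0.48 to -0.22 (standard error 0.52 and 0.68). The epithelial-mesenchymal transition call ended at an adjusted p of 0.0515, with its shift going from 0.34 to 0.26 (standard error 0.22 and 0.30). A lower share of epithelial cells would raise every other cell type alike, and of 9 lists of other types 6 were higher and 3 lower with an SD of 0.52 between their shifts (exact permutation p 0.103), which does not exclude it; the T and NK, macrophage and fibroblast levels together differed from the mast cell level by 1.61 (exact permutation p 0.0476; 1.14 without WD1), but these lists were chosen after their shifts were seen, so this p is too favourable. Fewer epithelial cells, array brightness and a change in the number or state of immune and stromal cells may all stay open beside chance. So may the maternal diet, which was not tested apart from them.

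The third pattern is the lower level of Esr1, Pgr, Prlr and Erbb2, by a mean of -0.98 (exact permutation p 0.0079, the smallest these groups allow; -0.93 with slide as a block, and -1.03, -0.62 and -1.30 within slides 1, 2 and 3). The 4 genes were fixed by name but grouped only after their values were seen, so this p is too favourable; the mean was -0.76 with Esr1 at its bound and -0.91 without Esr1. With brightness as a covariate the mean was -0.97 (95% interval of a linear model -1.60 to -0.34). The covariate thus left the mean nearly unchanged. The interval is too favourable because of that grouping. The mean also includes Esr1, which was not well above background on any Western-style diet array, and the covariate fit was not run without it. This test therefore cannot decide on brightness as the whole cause. The mean minus the luminal epithelial level was -0.82 (exact permutation p 0.0079), and -0.76 without Esr1. The luminal median member differed by -0.19 (SD 0.45, range -1.11 to 0.56). As the 4 genes were grouped after their low values were seen, a gap to an unselected list was likely in advance. This test therefore cannot decide on fewer luminal cells as the whole cause. Krt8 (-0.96) and Krt19 (-1.11), the luminal members of smallest p, were as low as the receptors, while 6 of the 15 luminal members were higher. Fewer luminal cells, a loss of 1 kind of luminal cell, array brightness and an effect of maternal diet may all remain open. These are hypotheses found on the same data.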

How the results depend on the processing

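The normexp forms, array brightness as a covariate and the 3 dimmest arrays left out were chosen only after the results were seen; the planned normexp on mean spot signals was not run. The count of genes at an adjusted p under 0.05 in limma was 0 under every alternative, and it is 2599 at an unadjusted p under 0.05 and 272 with a difference of at least 1 as well. The 10 called lists kept their sign under every alternative, and their calls held in these numbers of the 27 that used camera with the preset correlation: T and NK cell 27, fatty acid oxidation 25, macrophage 24, oxidative phosphorylation 24, fibroblast 23, cell cycle 22, inflammatory 20, MHC class II 20, mast cell 18 and epithelial-mesenchymal transition 15. Their sizes moved: over these 27 the shifts were T and NK cell 0.41 to 1.01, fatty acid oxidation -0.46 to -0.11, macrophage 0.28 to 1.00, oxidative phosphorylation -0.42 to -0.094, fibroblast 0.33 to 0.85, cell cycle -1.26 to -0.20, inflammatory 0.44 to 1.24, MHC class II 0.35 to 0.98, mast cell -1.62 to -0.52 and epithelial-mesenchymal transition 0.092 to 0.67. Apart from left-out tumours, the mast cell call ended with quantile normalisation (-0.99, adjusted p 0.0517), median scaling (-1.23, 0.0675), the series matrix (-0.62, 0.0540) and the filter on all arrays (-0.95, 0.0678). The epithelial-mesenchymal transition call ended with quantile normalisation (0.26, adjusted p 0.0564), normexp and quantile normalisation (0.21, 0.0682), the series matrix (0.21, 0.0713), the filter on 3 arrays (0.34, 0.0555) and brightness as a covariate (0.26, 0.0515), which also ended the cell cycle call (-0.22, 0.251). Without a filter the fibroblast (0.57, adjusted p 0.371), macrophage (0.54, 0.261), inflammatory (0.81, 0.142), MHC class II (0.54, 0.381) and epithelial-mesenchymal transition calls (0.40, 0.697) ended. The filter on all arrays ended the inflammatory (0.62, adjusted p 0.0678) and MHC class II calls (0.43, 0.148), and the fatty acid oxidation call ended without the 3 dimmest arrays (-0.14, 0.0528). Of the uncalled lists, left-out tumours and the values without a filter aside, adipocyte was called with brightness as a covariate (0.96, adjusted p 0.00398), fatty acid and triglyceride synthesis with slide as a block (-0.23, 0.0381) and with every probe tested (-0.27, 0.0123), and DNA repair without the 3 dimmest arrays (-0.24, 0.0407). Estrogen signalling was called with normexp (-0.17, adjusted p 0.0259), the replicate block (-0.33, 0.0474) and without the 3 dimmest arrays (-0.50, 0.0407), and epigenetic modifiers with the mean of a gene's probes (-0.18, 0.0427), every probe tested (-0.15, 0.0442) and without the 3 dimmest arrays (-0.19, 0.0407).

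Named genes kept their sign in all but 3 of 1994 comparisons. Most of them were picked for a small p, and the alternatives use the same arrays, so few changes of sign were possible. Camera with an estimated correlation called 0 lists and fry 0. With the replicate number as a block, 2673 genes had an unadjusted p under 0.05 and 11 lists were called. Deviations of tumours with the same number correlated by -0.02 to 0.16, and no tumour correlated best with its own number. The levels thus gave no sign that the numbers pair the samples, but so few correlations cannot exclude a pairing. The cause of the changes below was not tested, except that a filter or a left-out tumour changes the genes or samples tested, and median scaling and no filter moved the median difference of all genes to -0.24 and 0.34. Signal over background limits dim genes such as Esr1.

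Unadjusted p-value counts were 496 genes with normexp, 7050 without a filter and 961 with brightness as a covariate, and 18 lists were called without a filter, 5 of the 10 among them. List levels at an exact unadjusted p under 0.05 numbered 2, and 11 with median scaling, 0 with normexp, 5 with normexp and quantile normalisation, 6 with the series matrix, 7 without a filter, 7 with the filter on all arrays, 5 with that on 3 arrays and 6 without the 3 dimmest arrays. The exact permutation p of component 1 was 0.0238 with median scaling, 0.0397 without a filter and 0.0286 without the 3 dimmest arrays, and that of component 2 was 0.0238 and 0.0317 with the filters on all and on 3 arrays. The difference in spread was 0.0716 with normexp and quantile normalisation, 0.0719 with the series matrix and 0.0593 without a filter, and turned to -0.0054 with normexp and -0.046 without the 3 dimmest arrays.

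These shifts (log2) of lists that were not called, and of 2 named genes, had the other sign. With quantile normalisation they were neutrophil -0.025, interferon -0.0013 and trace element -0.024. With median scaling they were neutrophil -0.20, cholesterol -0.21, interferon -0.22, trace element -0.25, unfolded protein -0.14, immediate early -0.15, apoptosis -0.19 and adipokine -0.14. With normexp they were oxidative stress 0.064 and adipokine -0.00021, and with normexp and quantile normalisation interferon -0.0015, oxidative stress 0.025, trace element -0.023 and adipokine -0.033. With the series matrix they were interferon -0.0012, oxidative stress 0.026, trace element -0.035 and adipokine -0.063. Without a filter they were skeletal muscle 0.32, Schwann cell 0.14, milk protein 0.024, cholesterol -0.043, glycolysis 0.044, oncogenes 0.030, Wnt 0.11 and oxidative stress 0.10. With the filter on all arrays they were oxidative stress 0.037, circadian 0.072 and adipokine -0.21, and with that on 3 arrays cholesterol -0.035, Wnt 0.028 and trace element -0.0051. With the mean of a gene's probes they were cholesterol -0.0079 and trace element -0.033, and with every probe tested trace element -0.038 and adipokine -0.021. With slide as a block they were neutrophil -0.13 and glycolysis 0.077, and with array weights glycolysis 0.0054, Wnt 0.044 and oxidative stress 0.034. With brightness as a covariate they were neutrophil -0.040, Schwann cell 0.15, milk protein 0.70, cholesterol -0.00096, interferon -0.078, Wnt 0.19, Mfge8 0.077 and Krt5 0.097. Without the 3 dimmest arrays they were cholesterol -0.11, glycolysis 0.13, interferon -0.034, Wnt 0.077, oxidative stress 0.10 and Krt5 0.027.

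Leaving out each tumour in turn gave 1813 (without CD4) to 3222 (without CD3) genes at an unadjusted p under 0.05, and 1 (without WD1) to 10 called lists, with 4 without WD4, 5 without WD5 and 4 without CD5. List levels at an exact unadjusted p under 0.05 numbered 2 to 10 (the highest without WD2). The exact permutation p was 0.0159 (without CD3) to 0.373 for component 1 and 0.0238 (without WD3 or WD4) to 0.913 for component 2. The difference in spread was -0.00022 (without WD2) to 0.169 (without CD3). Shifts that changed sign were neutrophil -0.24 to 0.29, skeletal muscle -0.12 to 0.090, Schwann cell -0.11 to 0.099, milk protein -0.98 to 0.22, cholesterol -0.035 to 0.10, glycolysis -0.14 to 0.10, interferon -0.17 to 0.15, Wnt -0.20 to 0.0048, oxidative stress -0.064 to 0.087 and trace element -0.067 to 0.070.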

Other observations

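The relations with brightness and the look at component 3 and at the most variable genes were chosen only after the data were seen.

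Milk protein genes varied widely between tumours of both groups. Lalba, which makes the lactose synthase cofactor, ran from -4.15 in WD4 to 6.48 in CD1 (log2), and Csn1s1, a casein, from -2.87 in WD3 to 6.26 in CD1. Csn3, another casein, ran from -1.11 in WD4 to 6.67 in CD1, and Glycam1 from -4.56 in CD5 to 2.40 in CD2. Outside the milk genes, the imprinted transcript H19 ran from -3.88 in WD3 to 4.31 in WD4, and the chemokine Ccl3 was 3.96 in WD4 against -4.21 in CD1. The mast cell level was lowest in WD1, at -1.30, and highest in CD5, at 2.41. These genes were named after their values were seen.

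Component 3 (15.9% of the variance) differed between groups by 36.9 with an exact permutation p of 0.0238, which is 0.0714 after Benjamini-Hochberg adjustment over 3 components. The difference was 31.1, 29.7 and 28.6 within slides 1, 2 and 3. A permutation test between slides gave p = 0.05.

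Across the 10 arrays, brightness was compared with the levels of 35 lists. Epigenetic modifiers had the strongest relation, with Pearson r = 0.80 (permutation p 0.00477, adjusted p 0.167) and Spearman rho = 0.85 (permutation p 0.00257). The Pearson value was 0.79 without the 2 arrays farthest from the median brightness, 0.77 after centring on slides and 0.64 within groups. No relation passed the adjustment over 35 lists.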
